A study of Homo sapiens with 6 samples.

How the data were processed

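RNA was taken from PMA-differentiated THP-1 cells after 24 h with CXCL10 or control solution, with 3 libraries in each group. Per the labels, polyadenylated RNA was made into libraries with a stranded Illumina mRNA ligation kit and sequenced on a NovaSeq X Plus. Per the submitters' processing notes, the tools were Trim Galore, STAR, Subread and featureCounts with the genome build hg38; versions other than that of featureCounts are not given in the sources used here. Each deposited file holds raw read counts per gene for 1 library, made by the authors with featureCounts 2.0.6 on the exons of the GENCODE 30 annotation, per the file headers. No normalization had been applied to them.

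The command line in the file headers shows several settings that bear on the counts. Paired mode was on without counting of pairs, so both mates of a fragment were counted and 1 fragment inside a gene's exons gives 2 reads. This made even counts more common: among genes with low counts (1 to 20 reads), 66.8% to 75.8% of the counts per library were even. Counts treated as independent reads therefore overstate the number of molecules. The limit given for a gene without reads covers counting error only. Standard errors and intervals of fold changes come from edgeR's fit described below, which also takes in the spread between libraries. No strand was set although the kit marks strand, so reads of a gene and of an antisense neighbour cannot be told apart. Reads over 2 genes and reads mapped to several places were left out, which lowers overlapping genes and genes with near-identical copies. Genes were keyed by name, so genes of the same name were merged; 150 of the 57316 names lay on more than 1 chromosome.

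Library totals were 38.9, 38.0 and 36.0 M reads for control replicates 1, 3 and 4 and 36.9, 41.0 and 34.8 M reads for CXCL10 replicates 1, 3 and 4. A limit of 3 fragments, which is up to 6 reads because both mates are counted, corresponds to 0.146 to 0.173 CPM. No pair of libraries held identical counts or agreed within sampling noise.

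Groups were taken from the labels. Differences were tested with edgeR 4.0.16 in R 4.3.3: edgeR's filterByExpr on the groups, TMM factors, a quasi-likelihood fit with the group as the only term over all 6 libraries, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. Standard errors were derived from the fitted log2 fold change and its F statistic. CPM values of genes were computed here from the deposited counts, with the totals of the filtered genes scaled by the TMM factors. They are given as mean ± SD over 3 libraries. Shares of reads and the limit of 3 fragments used the unscaled library totals. The test was checked on simulated counts, with 50 genes at each of 4 fold changes. Counts were drawn from the real means, the dispersion trend over expression and the library sizes. Genes were simulated independently of each other, without single-gene dispersions, an outlying library or trends with gene length or GC. The test recovered 11 of 50 genes changed 1.5-fold, 33 of 50 changed 2-fold, 40 of 50 changed 3-fold and 47 of 50 changed 4-fold. It also called 6 unchanged genes. With no gene changed it called 0.

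Gene lists were textbook groups of macrophage, stress, metabolic and RNA quality genes and of markers for other cell types, 43 in all. The 41 with at least 5 tested members were tested with limma 3.58.1's camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the lists. An estimated correlation and limma's fry test were alternatives. Members were also counted with their p-values adjusted over the list alone. List scores per library are means over members of log2 CPM relative to the mean of all libraries, compared by an exact two-sided permutation test, whose smallest p here is 0.1. Symbols were matched to the names in the count files, with older symbols where needed, and 2 listed symbols were not used here.

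The lists, tests, most of the other settings and the rule for named genes were fixed before the data were examined. The rule takes CXCR3, CXCL9, CXCL10 and CXCL11 in any case. It takes up to 10 genes per direction with the largest change among those past the threshold, with a mean of at least 1 CPM, no overlap between groups and a protein-coding symbol. From each list it takes up to 4 members past the threshold. Where fewer than 5 genes qualify in a direction, it takes the 5 with the lowest p-value under the same level and symbol conditions, stated as not past the test. Here no gene qualified under the threshold, so the 4 fixed genes and 5 genes per direction are given.

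Other settings fixed in advance were DESeq2's size factors, upper-quartile factors, library size only, no filter on low counts, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, removal of the gene length trend, thresholds of 0.01 and 0.1, and each library left out in turn. Added after the data were seen were halved counts, limma-voom with library quality weights, a robust fit, removal of GC and length trends, and list tests without the length trend and without control replicate 4. Gene types and GC content came from GENCODE 29, a release before that of the counts, matched by name, and 99.2% of tested genes had their own GC value. Gene positions and exon lengths are those of the count files (hg38, counted from 1). The shared exon length of neighbouring genes was computed from the same positions. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.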

Results

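Gene expression was measured in THP-1 cells, a human monocytic leukaemia line that takes on macrophage features when exposed to the phorbol ester PMA. The cells had received PMA at 100 ng/ml for 48 h. They were then kept for 24 h with recombinant human CXCL10 at 100 ng/ml or with a control solution. CXCL10 is an interferon-inducible chemokine that binds the receptor CXCR3. Polyadenylated RNA was sequenced from 3 control and 3 CXCL10 libraries, which carry the replicate numbers 1, 3 and 4 in both groups. The deposited gene counts summed to 37.6 ± 1.46 M reads per control library and 37.6 ± 3.18 M reads per CXCL10 library (mean ± SD, n = 3 each), with a range from 34.8 to 41.0 M reads. The most abundant transcript was that of SPP1, which encodes the secreted phosphoprotein osteopontin, with 1.78% of all reads, followed by the ferritin light chain gene FTL with 1.15%. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

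The comparison of CXCL10 with control asked which transcripts differ in macrophage-like cells after a day with this chemokine. Lower with CXCL10 as groups were the genes of cytosolic ribosomal proteins (43 tested, median log2 fold change -0.41), the nuclear-encoded genes of oxidative phosphorylation (46 tested, median -0.35), nuclear-retained and small-RNA-host noncoding RNAs (13 tested, median -0.29), and metallothionein and zinc-response genes (7 tested, median -0.38). These 4 of 41 gene lists passed limma's camera test with a preset correlation between genes, and 0 passed with an estimated correlation (lowest adjusted p = 0.667). The preset was 0.01, and the estimates were 0.86, 0.51, 0.03 and -0.08 in the order above. Of the 10 splits of the 6 libraries into 3 and 3, 6 called at least 4 lists, the real one among them. The highest other split called 10 lists. The ribosomal protein and noncoding RNA lists had been set up as measures of RNA quality. Control replicate 4, which stood apart from the other libraries, had the highest score in the first 3 of the 4 called lists (0.55, 0.42 and 0.26 on the log2 scale relative to the mean of all libraries). No single gene passed the test over all genes: edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower among 16531, and its lowest adjusted p was 0.683.

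At an unadjusted p under 0.05, edgeR counted 1181 genes, of which 413 were higher and 768 lower with CXCL10, where 827 would be counted with no effect. The other 9 splits of the 6 libraries into 3 and 3 gave from 212 to 1683 such genes, and 2 of them gave more than the real split. Scaled by library size alone, edgeR counted 1151 genes, 744 higher and 407 lower. DESeq2 and limma-voom also called 0 genes, with 1283 and 1182 at an unadjusted p under 0.05. The edgeR count was 649 without control replicate 4 (376 higher and 273 lower) and 626 without CXCL10 replicate 3 (298 and 328). It was 649 without CXCL10 replicate 4 (310 and 339) and 2103 without CXCL10 replicate 1 (902 and 1201). All 3 CXCL10 libraries lay on one side of all 3 controls for 2024 genes, or 12.2%, where chance gives 10%. Calls appeared in 2 settings. With no filter on low counts, edgeR called 45 genes higher and 92 lower, and limma-voom with weights for library quality, chosen after the data were seen, called 11 higher and 31 lower. The biological coefficient of variation was 17.4%, and the 95% interval of the log2 fold change lay between -1 and 1 for 12303 genes, or 74.4% of those tested. Among simulated genes with a known change, the same test at this depth recovered 66% of those changed 2-fold and 94% of those changed 4-fold. The simulation held no correlation between genes, no outlying library and no length trend, so recovery in the real libraries may be lower.

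The receptor and ligands of the CXCL10 axis were expressed at low levels, and with all 6 libraries their differences stayed within the spread between libraries in edgeR's test. Without control replicate 4, 1 of the 3 tested genes had an unadjusted p under 0.05 by edgeR, and 0 passed after adjustment. The same counts came with the length trend removed as well, and from limma-voom with library quality weights. CXCR3, the receptor (chromosome X, 71615916 to 71618511, hg38), measured 2.002 ± 0.137 CPM in controls and 1.73 ± 0.433 CPM with CXCL10 (n = 3 each), from 53 to 82 reads per library. Its log2 fold change was -0.22 ± 0.28 (SE, adjusted p = 0.882 by edgeR), which was -0.01 without CXCL10 replicate 3 and -0.33 without CXCL10 replicate 1. The CXCL10 transcript itself (chromosome 4, 76021118 to 76023497) had 18 to 144 reads per library and a log2 fold change of 0.26 ± 0.49 (adjusted p = 0.930 by edgeR). That value was -0.15 without control replicate 4, -0.29 without CXCL10 replicate 3, 0.56 without CXCL10 replicate 4 and 0.90 without control replicate 1. CXCL11 (chromosome 4, 76033682 to 76041415), another CXCR3 ligand, had 2 to 60 reads per library and a log2 fold change of -0.48 ± 0.69 (adjusted p = 0.894 by edgeR), which ran from -1.02 without control replicate 4 to 0.18 without control replicate 1. CXCL9, the remaining interferon-inducible CXCR3 ligand (chromosome 4, 76001275 to 76007488), had 0 reads in all 6 libraries, which allows up to 0.146 to 0.173 CPM per library. That limit, which corresponds to 3 fragments or up to 6 reads, covers counting error only. The 11 tested genes of the whole receptor axis had a median log2 fold change of -0.02 (camera adjusted p = 0.997).

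**Figure D1:**
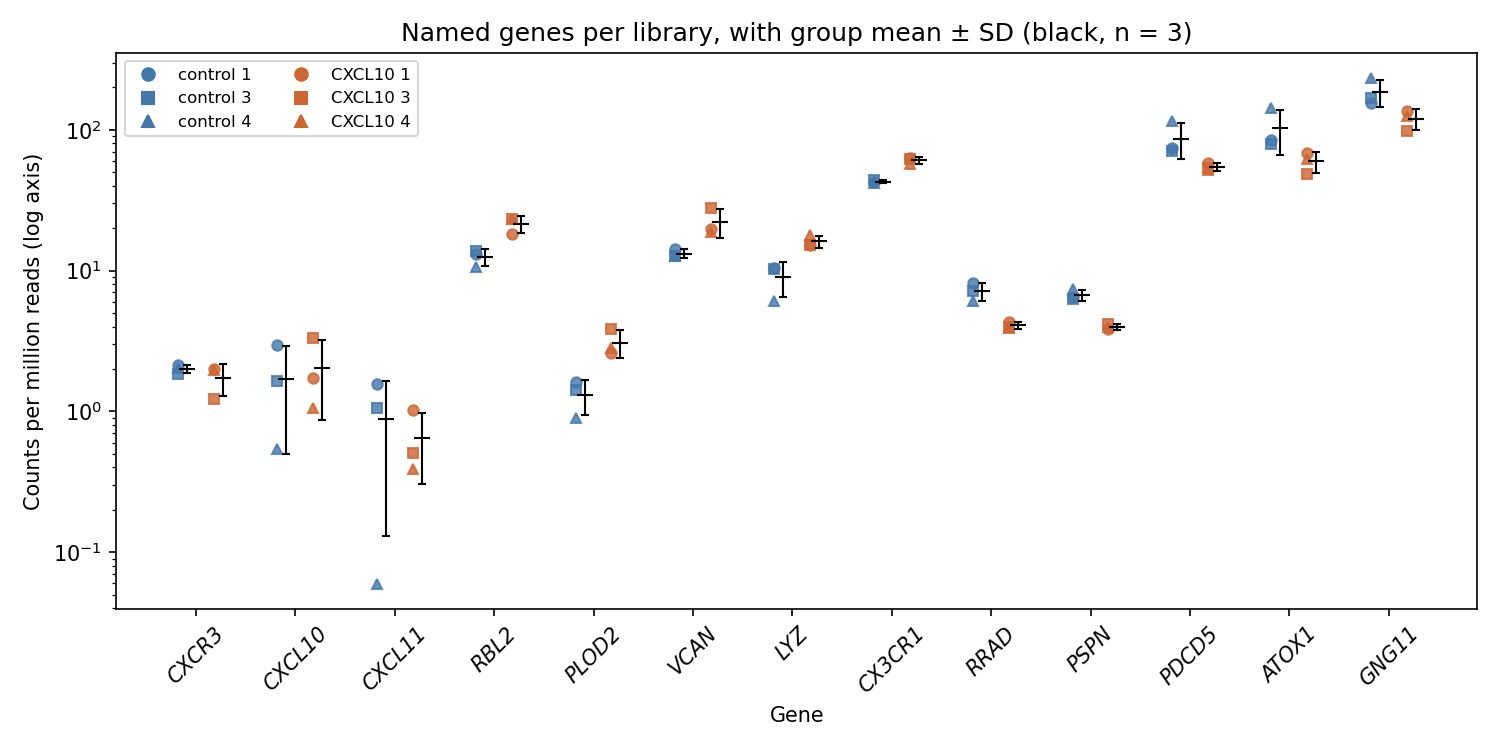
Expression in CPM (log axis) of 13 named genes in each of the 3 control and 3 CXCL10 libraries, with the replicate number as the symbol and the group mean ± SD in black (n = 3). CXCR3, CXCL10 and CXCL11 overlap between the groups, and the other 10 genes, chosen for their low p-values, do not overlap, although none passed the test over all genes (lowest adjusted p 0.683).

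The 5 genes with the lowest p-values in each direction separated the groups without overlap, yet all had an adjusted p of 0.683 in edgeR's test. On the higher side were RBL2, LYZ, VCAN, PLOD2 and CX3CR1. RBL2, which encodes the pocket protein p130 of the retinoblastoma family (chromosome 16, 53433977 to 53491648), measured 12.5 ± 1.67 CPM in controls and 21.5 ± 3.005 CPM with CXCL10, a log2 fold change of 0.78 ± 0.17 (SE). LYZ, the lysozyme gene (chromosome 12, 69348341 to 69354234), measured 8.96 ± 2.45 and 16.1 ± 1.60 CPM, with a log2 fold change of 0.85 ± 0.20. VCAN, which encodes the matrix proteoglycan versican (chromosome 5, 83471618 to 83582303), measured 13.2 ± 0.904 and 22.1 ± 5.06 CPM, with a log2 fold change of 0.74 ± 0.18. PLOD2, which encodes a lysyl hydroxylase of collagen (chromosome 3, 146069440 to 146163653), had the largest difference of the 10 genes, at 1.23 ± 0.29 from a control level of 1.31 ± 0.368 CPM. CX3CR1, the fractalkine receptor (chromosome 3, 39263494 to 39281735), had the smallest at 0.50 ± 0.13, with 42.8 ± 0.903 CPM in controls and 60.5 ± 3.07 CPM with CXCL10. Control replicate 4 was the lowest library for all 5 of these genes. Without it the log2 fold changes of PLOD2, RBL2 and VCAN were 1.03, 0.68 and 0.71. That of VCAN was 0.55 without CXCL10 replicate 3. Counting ignored strand and left out reads over 2 genes. As 34.0% of the exon length of LYZ and 18.3% of that of RBL2 lie opposite another annotated gene, their levels may be too low.

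The 5 genes on the lower side were RRAD, PSPN, PDCD5, ATOX1 and GNG11. RRAD, which encodes a Ras-related GTPase (chromosome 16, 66921679 to 66925536), measured 7.13 ± 1.01 CPM in controls and 4.08 ± 0.209 CPM with CXCL10, a log2 fold change of -0.81 ± 0.19 (SE). PSPN, the gene of the neurotrophic factor persephin (chromosome 19, 6375148 to 6379058), measured 6.71 ± 0.617 and 3.99 ± 0.188 CPM, with a log2 fold change of -0.75 ± 0.19. PDCD5 (chromosome 19, 32581190 to 32587453), ATOX1, which encodes a copper chaperone (chromosome 5, 151742316 to 151772532), and GNG11, which encodes a G protein gamma subunit (chromosome 7, 93921699 to 93928610), had log2 fold changes of -0.66 ± 0.17, -0.78 ± 0.21 and -0.63 ± 0.17. For these 3 genes control replicate 4 was the highest library, with 114, 143 and 232 CPM against control means of 86.5, 102 and 185 CPM, and without it their log2 fold changes were -0.41, -0.45 and -0.43.

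Ribosomal protein transcripts were lower with CXCL10 as a group, with all 43 tested genes below 0 (camera adjusted p = 6.07e-18, and 0.836 with an estimated correlation). None of the 43 passed the test over all genes, and 32 passed when adjusted over the list alone. The genes moved together across libraries (estimated correlation 0.86), so the 32 are not independent results. RPS12 measured 1342 ± 417 CPM in controls and 886 ± 115 CPM with CXCL10, and RPL11 measured 1343 ± 431 and 895 ± 69.5 CPM. As a share of all reads, ribosomal protein genes took 10.8% ± 1.78 in controls and 8.56% ± 0.986 with CXCL10 (n = 3 each). Control replicate 4 had the highest share at 12.8% and CXCL10 replicate 3 the lowest at 7.67%, while CXCL10 replicate 1, at 9.62%, lay beside controls 1 and 3 at 9.85% and 9.67%. Without control replicate 4 the median log2 fold change was -0.24, still past the preset-correlation test (adjusted p = 1.43e-10, and 0.865 with an estimated correlation). The mean list score did not overlap between the groups, and its exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries can give. Ribosomal protein genes have many processed pseudogenes, and reads that map to several places were left out of the counts, so their absolute levels are uncertain.

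Oxidative phosphorylation genes encoded in the nucleus showed the same direction, with 41 of 46 below 0 (camera adjusted p = 8.52e-11, and 0.836 with an estimated correlation). None passed over all genes or when adjusted over the list alone, and 22 had an unadjusted p under 0.05. COX6B1, a subunit of cytochrome c oxidase, had a log2 fold change of -0.57 ± 0.18, from 387 ± 102 to 261 ± 46.2 CPM, and ATP5PO, a subunit of ATP synthase, had -0.85 ± 0.25. Here too control replicate 4 was the highest library, and the median was -0.19 without it, still past the preset-correlation test (adjusted p = 7.10e-06, and 0.865 with an estimated correlation). The list scores overlapped between the groups, with CXCL10 replicate 1 above control replicate 3, and their exact two-sided permutation p was 0.2. The 13 mRNAs encoded in the mitochondrial genome had a median of -0.02 (camera adjusted p = 0.916), which was 0.05 without CXCL10 replicate 3, and a mean of 0.04. With the gene length trend of each library removed they were called higher (median 0.16, adjusted p = 1.16e-04, and 0.943 with an estimated correlation). Mitochondrial genes took 5.20% ± 0.135 of reads in controls and 5.17% ± 0.573 with CXCL10.

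Metallothionein and zinc-response genes were lower as a group (camera adjusted p = 0.00721, and 0.667 with an estimated correlation). The tested members were 6 genes of metallothioneins, which bind zinc and copper, and SLC30A1, which encodes a zinc exporter and had a log2 fold change of 0.14. Of 7 tested members 5 were below 0, and 1 of them, MT1E, passed when adjusted over the list alone, with 6.06 ± 0.671 CPM in controls and 3.62 ± 0.745 CPM with CXCL10. MT1G had a log2 fold change of -0.69 ± 0.29 and MT2A of -0.37 ± 0.17. Every control library had a higher list score than every CXCL10 library, with an exact two-sided permutation p of 0.1, the smallest possible. The list was no longer called without control replicate 3 (median -0.37, adjusted p = 0.0713), with the gene length trend removed (median -0.25, adjusted p = 0.726) or with GC and length trends removed (median -0.28, adjusted p = 0.428). With the length trend removed and without control replicate 4 it was called (median -0.29, adjusted p = 0.0371, and 0.899 with an estimated correlation). The MT1 genes are close copies of each other, so reads that fit several of them are missing from these counts.

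Among nuclear-retained and small-RNA-host noncoding RNAs, 10 of 13 were below 0 (camera adjusted p = 0.00489, and 0.667 with an estimated correlation), and 5 passed when adjusted over the list alone. The members with the lowest p-values were host genes of small nucleolar RNAs: SNHG5 had a log2 fold change of -0.56 ± 0.17, from 415 ± 99.5 to 281 ± 46.8 CPM, ZFAS1 had -0.81 ± 0.25, and GAS5 had -0.40 ± 0.16. MALAT1, a nuclear-retained RNA of the same list, had 0.64 ± 0.35 in the opposite direction and did not pass. Without CXCL10 replicate 1 the list was no longer called, with a median of -0.33 (adjusted p = 0.0706). The list scores overlapped between the groups, with CXCL10 replicate 3 above control replicate 3 (exact two-sided permutation p = 0.2). Exons of ZFAS1 share 26.1% of their length with genes on the opposite strand, which the counting could not separate.

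**Figure D2:**
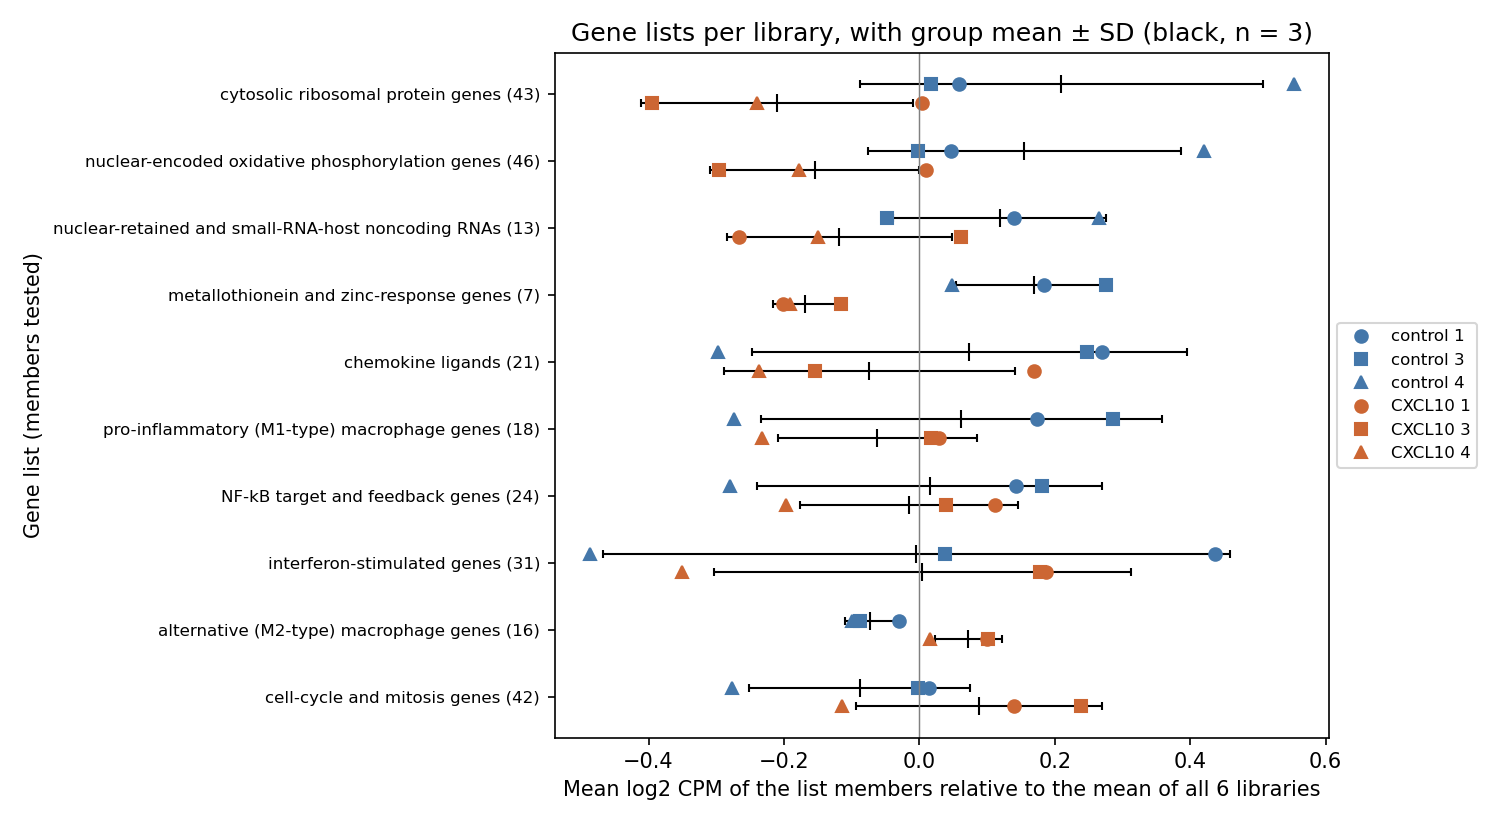
Mean log2 CPM of the members of 10 gene lists in each library, relative to the mean of all 6 libraries, with the replicate number as the symbol and the group mean ± SD in black (n = 3). Control replicate 4 lies at 0.55 for ribosomal protein genes and CXCL10 replicate 3 at -0.39, while controls 1 and 3 and CXCL10 replicate 1 lie between 0.00 and 0.06.

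Inflammatory programs were not called in either direction with all 6 libraries. Chemokine ligands had a median log2 fold change of -0.25 over 21 genes (camera adjusted p = 0.207). Pro-inflammatory M1-type genes had -0.18 over 18 genes (adjusted p = 0.301), NF-kB target and feedback genes -0.06 over 24 genes (adjusted p = 0.523) and interferon-stimulated genes -0.07 over 31 genes (adjusted p = 0.773). IL1B, the interleukin-1 beta gene, was the most abundant of the named members, with 1144 ± 134 CPM in controls and 852 ± 146 CPM with CXCL10 and a log2 fold change of -0.42 ± 0.15. CCL20 measured 105 ± 35.9 and 72.9 ± 3.64 CPM, and ISG15 measured 27.2 ± 6.93 and 19.4 ± 6.56 CPM. Control replicate 4 had the lowest score of all 6 libraries in each of these 4 lists. Without it, all 4 were called lower by camera with the preset correlation, with medians of -0.31 for chemokine ligands, -0.36 for M1-type genes, -0.18 for NF-kB targets and -0.25 for interferon-stimulated genes (adjusted p = 1.47e-04, 0.00299, 0.00358 and 0.00184). With an estimated correlation none of the 4 was called there (adjusted p from 0.849 to 0.920). Chemokine ligands were also called lower without CXCL10 replicate 1 (median -0.37, adjusted p = 0.0225, and 0.901 with an estimated correlation). Their median was -0.15 without CXCL10 replicate 3, -0.16 without CXCL10 replicate 4 and -0.13 with the gene length trend removed, with no call. With other libraries left out, and no call, the median turned above 0 for 3 of the lists. It was 0.17 for interferon-stimulated and 0.05 for NF-kB genes without control replicate 1, 0.13 and 0.09 without CXCL10 replicate 4, and 0.02 for both NF-kB and M1-type genes without control replicate 3. Scaled by library size alone, the NF-kB and interferon-stimulated medians were 0.02 and 0.01.

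Genes of alternative, M2-type macrophages had a median log2 fold change of 0.11, with 13 of 16 above 0 (camera adjusted p = 0.194), which was 0.19 without control replicate 3 and 0.18 scaled by library size alone. CD163, a haemoglobin scavenger receptor, measured 50.4 ± 3.03 CPM in controls and 61.6 ± 7.69 CPM with CXCL10. MERTK, a receptor kinase for the uptake of apoptotic cells, is not in that list, and measured 53.7 ± 4.56 and 66.9 ± 5.73 CPM. It belongs to the phagocytosis and scavenger receptors, a list that was not called (median 0.10, camera adjusted p = 0.301). Extracellular matrix genes had a median of 0.11 (adjusted p = 0.0734) and were called higher without CXCL10 replicate 3 (adjusted p = 0.0330, and 0.923 with an estimated correlation), and VCAN was the 1 member past the test when adjusted over the list alone. CX3CR1 was likewise the 1 such member among chemokine and chemoattractant receptors, whose median was 0.09 (adjusted p = 0.769), -0.01 without control replicate 1 and -0.07 without CXCL10 replicate 4. Cell-cycle and mitosis genes had a median of 0.10, with 32 of 42 above 0 (adjusted p = 0.0627, and 0.997 with an estimated correlation), which was 0.05 without control replicate 4, 0.16 without control replicate 3 and 0.19 without CXCL10 replicate 4. They were called higher in 9 of the other settings and not in another 9. Among the calls were those without control replicate 1 (adjusted p = 0.0335), without CXCL10 replicate 4 (3.85e-05), with at least 1 CPM in 3 libraries (0.0324), and with the length trend (0.00211) or GC and length trends (0.00270) removed. In none of these 5 named settings were they called with an estimated correlation (adjusted p from 0.943 to 0.989). Markers of other cell types were not called: the medians were -0.34 for neutrophil and immature myeloid granule genes (adjusted p = 0.523), 0.06 for T and NK cells (0.997), 0.02 for B and plasma cells (0.997), -0.07 for fibroblasts (0.997) and -0.06 for endothelial cells (0.997). The T and NK, B and plasma and fibroblast medians changed sign with some single libraries left out, and the fibroblast and endothelial medians with scaling by library size alone. The granule genes had a median of 0.13 without control replicate 4, and with the length trend removed as well they were called higher (0.14, adjusted p = 0.0360, and 0.899 with an estimated correlation). For fibroblast and endothelial markers the mean was above 0 (both 0.02) while the median and camera's direction were below it, and for B and plasma cells camera's direction was below a median and mean above 0. The member examples given for the lists were chosen after their values were seen.

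Control replicate 4 stood apart from the other 5 libraries. The first principal component, with 44.2% of the variance, placed it at 66.6 and the others between -19.6 and -6.11. It had counts for 21546 genes, against 23631 to 24807 in the other libraries. Fold changes also followed gene length: the median log2 fold change was -0.18 in the 1 of 5 equal groups of genes with the shortest exons and 0.11 in the group with the longest, with a Spearman correlation of 0.32 across genes, which are not independent replicates. By GC content, CXCL10 replicates 1 and 3 ran in opposite directions. From the group of lowest GC to that of highest, their median deviations went from -0.17 to 0.13 and from 0.28 to -0.14. Control replicate 4 went from 0.01 to -0.04.

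**Figure D3:**
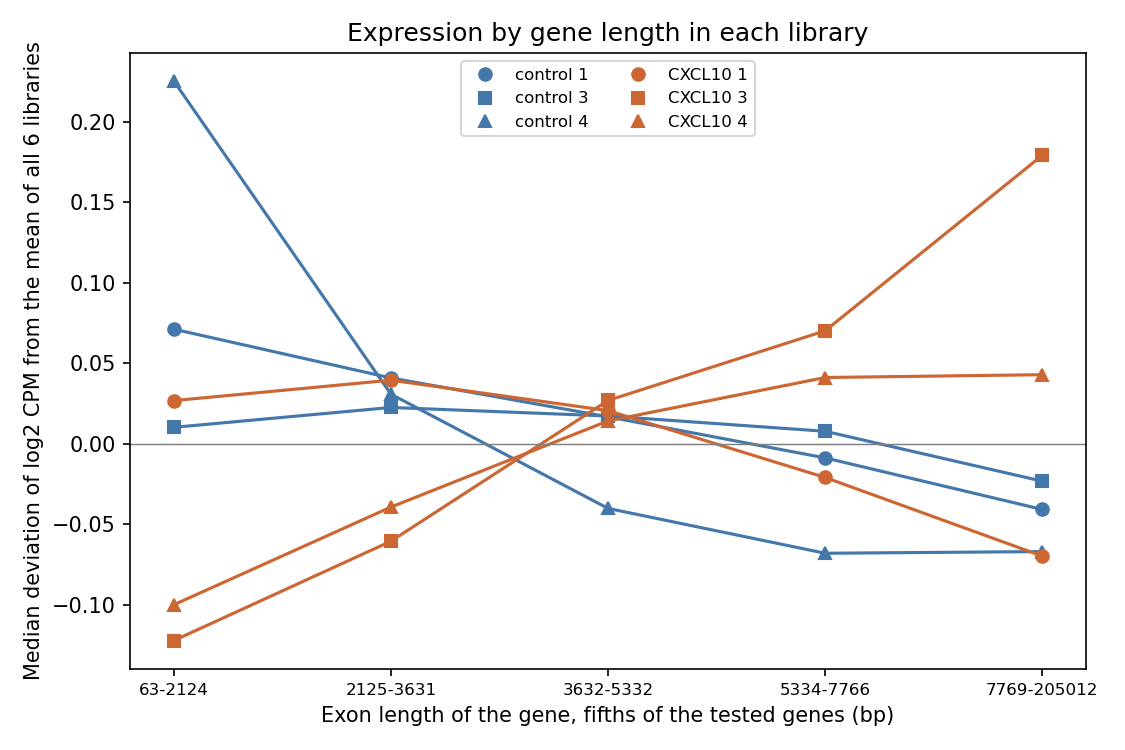
Median deviation of log2 CPM from the mean of all 6 libraries, for 5 equal groups of the tested genes by exon length in base pairs, with 1 line per library. In the shortest group control replicate 4 lies at 0.23, CXCL10 replicates 3 and 4 lie at -0.12 and -0.10, and in the longest group CXCL10 replicate 3 lies at 0.18.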

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

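Chosen only after the data were seen were the settings with halved counts, library quality weights, a robust fit, GC and length removal, and, for lists, length removal and its combination with leaving out control replicate 4. The counts of 0 genes higher and 0 lower were kept with other scaling, a stricter filter, DESeq2, limma-voom, halved counts, a robust fit, length and GC removal, thresholds of 0.01 and 0.1, and each library left out (lowest and highest 0). With no filter on low counts edgeR called 45 higher and 92 lower, 132 of them among the genes tested with the filter, while another split of the 6 libraries gave 187 calls. With quality weights 11 were higher and 31 lower, and the other splits gave 0. The 2 settings shared 8 genes, and the cause was not tested. Gene lists called were 4, and 3 to 10 with a library left out: 10 without control replicate 4, 9 when the length trend of each library was removed as well, 0 with an estimated correlation, and 0 with fry for either direction or mixed changes. Libraries of the same replicate number showed no shared deviation (correlations of deviations 0.03, 0.02 and -0.05). With so few libraries, and no pairing stated in the labels, this does not settle whether they were paired. A replicate block gave 0 genes higher, 0 lower and 5 lists, the added one being cell-cycle genes, higher (adjusted p = 0.0236, and 0.973 with an estimated correlation). Length removal also gave 5 lists, without the metallothionein list and with cell-cycle genes (adjusted p = 0.00211) and mitochondrially encoded mRNAs, both higher and both at 0.943 with an estimated correlation. Of the values given for named genes, 268 kept their side of the threshold and direction, 12 passed the threshold in the 2 settings above and 6 changed sign, none of them past it. The CXCL10 gene was -0.65 with quality weights, -0.035 with length removal and without control replicate 4, and from -0.29 to 0.90 with a library left out. CXCL11 was -1.23 with quality weights, 0.18 with limma-voom, and from -1.02 to 0.18 with a library left out. With the replicate block CXCL11 was -0.16, and -0.05 with length removal as well. List medians with a library left out ran from -0.37 to -0.15 for chemokine ligands, -0.36 to 0.023 for M1-type genes, -0.18 to 0.088 for NF-kB genes, -0.25 to 0.17 for interferon-stimulated genes and -0.12 to 0.048 for mitochondrially encoded mRNAs. With library size only, NF-kB genes had a median of 0.019, interferon-stimulated genes 0.014 and mitochondrially encoded mRNAs 0.057. The mitochondrial list was called higher with length removed (median 0.16, adjusted p = 1.16e-04, and 0.15 and 0.00116 with the replicate block), with GC and length removed (0.069 and 0.00361, or 0.061 and 0.0139 with the block) and with length removed and without control replicate 4 (0.095 and 0.0118). None of these calls held with an estimated correlation (adjusted p from 0.899 to 0.988), and the cause was not tested. The metallothionein and zinc-response list was no longer called with length removed (-0.25, adjusted p = 0.726, in a range over settings from 0.000460 to 0.726, and 0.634 with the block) or with GC and length removed (0.428, and 0.381 with the block). Low read numbers limit CXCL9, CXCL10 and CXCL11, with 0 to 144 reads per library. With halved counts CXCL10 was 0.26 and CXCL11 -0.50. Halving scales all libraries alike and could hardly move a fold change, so it does not test how far low read numbers limit these genes.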

Other observations

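Several single genes passed the threshold when libraries were weighted by their quality, a setting added after the data were seen. It called 31 genes lower, among them IL32, which encodes a pro-inflammatory cytokine (-0.97 against -0.66 in the unweighted edgeR fit), EBI3, a cytokine subunit (-0.96 against -0.40), CCL20 (-0.74 against -0.52), the lipid-handling genes FABP4 (-0.76 against -0.34) and APOC1 (-0.82 against -0.32), and the matrix metalloproteinase MMP1 (-0.59 against -0.53). The 11 genes called higher included RBL2, LYZ, CX3CR1, APAF1, which encodes a scaffold of the apoptosome (0.86 against 0.96), and AHNAK2 (0.78 against 0.70). All of these genes, chosen as examples after their values were seen, had an adjusted p of 0.683 or more in edgeR's test without weights. In CPM the groups overlapped for EBI3, CCL20, FABP4 and APOC1, and did not for IL32, MMP1 and the named higher genes. Other lower calls were near the floor: ADAMTS3, EBF3, SPATC1, BEST4 and AC131009.2 had means of 0.27 to 0.46 CPM, with 0 CPM in CXCL10 replicate 4. The weights ranged from 0.321 for control replicate 4, 0.486 for CXCL10 replicate 1 and 0.501 for CXCL10 replicate 3 to 1.77, 2.40 and 3.01 for control replicates 3 and 1 and CXCL10 replicate 4, so CXCL10 replicate 4 carries most of the treated side. Of the other 9 splits of the 6 libraries none gave a call in this setting, and 10 splits are too few for a share under 0.05.

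Matrix-related genes gave mixed values. ADAM9 and ADAM17, which encode membrane sheddases, measured 30.1 ± 16.9 and 27.6 ± 12.6 CPM in controls and 63.0 ± 13.6 and 46.0 ± 7.10 CPM with CXCL10, while MMP1 measured 196 ± 17.7 and 136 ± 39.5 CPM and SPP1 had a log2 fold change of -0.07 ± 0.13. AREG, the growth factor amphiregulin, had -0.54. None of them passed edgeR's test over all genes, and the matrix-remodelling list was not called (median -0.06, camera adjusted p = 0.773), although it was without control replicate 4 (lower, -0.09, adjusted p = 0.0285, and 0.849 with an estimated correlation). Lists for cholesterol synthesis (median 0.07, adjusted p = 0.769), lipid uptake and storage (0.07, 0.997), lysosomes (0.01, 0.916), glycolysis and hypoxia (-0.01, 0.997) and class I antigen presentation (-0.13, 0.393) were not called either. Class I genes were called lower without CXCL10 replicate 1 (-0.25, adjusted p = 0.0265, and 0.845 with an estimated correlation). For lipid uptake and lysosomes camera's direction was below a median above 0.

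The tests below that were chosen only after the result was seen are the removal of control replicate 4, alone for ribosomal protein genes and together with the length trend, the permutation of the list score for ribosomal protein genes, and the variance explained by GC content and length for control replicate 4, which replaced an earlier test that could not decide. Leaving out each library in turn was itself fixed in advance, but its use as a test of that library as the source was not. The 10 possible splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. All 10 gave 0 genes higher and all 10 gave 0 genes lower, so the highest other value was 0. For gene lists, 6 of the 10 splits called at least as many as the real 4, and the highest other split called 10.

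The lower ribosomal protein transcripts were weighed first. The gene length trend was tested with 1000 random gene sets matched on exon length and expression. Of these, 0% had a median as low as -0.41, and the lowest median was -0.17. This argues against a trend with that exon length as the whole source. The length counts all annotated exons of a gene (median 3393 bp in the list and 3436 bp in the matched genes). It can exceed that of the expressed transcript, so a trend with transcript length was not tested. Control replicate 4 as the source stays open: without it the median was -0.24, called with the preset correlation but not with an estimated one (adjusted p = 0.865 with an estimated correlation), and with the length trend removed as well it was -0.20 (adjusted p = 8.00e-06, and 0.899 with an estimated correlation). Another split of the 6 libraries, with control replicates 1 and 4 and CXCL10 replicate 1 on the control side, gave a median of -0.41, as low as the real one, and one with control replicate 1 and CXCL10 replicates 3 and 4 on that side gave 0.39. A difference in quality or RNA composition between single libraries stays open together with an effect of CXCL10, because the exact permutation p of 0.1 is the smallest possible and CXCL10 replicate 1 lay beside 2 of the controls.

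The second pattern is control replicate 4, the library farthest from the rest, where few distinct molecules would widen the spread mainly at low expression. Its median absolute deviation was 1.43 times the highest of the other libraries below 10 CPM, 0.97 times from 10 to 50 CPM, 1.08 times from 50 to 100 CPM, 1.17 times from 100 to 500 CPM and 1.76 times at 500 CPM or more, and this last value argues against few molecules as the whole source. Its lower number of detected genes goes with few molecules. Even counts were also more common there, with 75.8% against 66.8% to 68.0% at 1 to 20 reads and 59.3% against 52.6% to 54.4% at 200 to 2000 reads. They arise where both mates of a fragment are counted, and a link to the number of molecules was not tested. GC content and exon length explained 16.6% of the variance of the deviation of control replicate 4 from the other controls, over the 8754 genes of at least 10 CPM. The same measure gave 19.8% and 12.4% for control replicates 1 and 3. It gave 30.2%, 44.5% and 23.3% for CXCL10 replicates 1, 3 and 4 against all 3 controls. In control replicate 4 the share is too little for these trends, with length over all annotated exons, to be the main source. Genes below 10 CPM were not part of this test. A larger share of undifferentiated cells stays open as a candidate explanation, since granule genes of immature myeloid cells were higher there (median deviation 0.90, AZU1 98.0 CPM against 54.1 and 50.8) but the progenitor gene MYB, counted in that median of 5 genes, was not (deviation -0.10, 3.53 CPM against 3.36 and 4.26), and cell-cycle genes had a median deviation of -0.18 with a spread of 0.31, and the design gives no biological explanation for a single control library.

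The third pattern is that chemokine, M1-type, NF-kB and interferon-stimulated genes were called lower together with the preset correlation once control replicate 4 was left out, chemokine ligands also without CXCL10 replicate 1, while none of these calls held with an estimated correlation (adjusted p from 0.849 to 0.920). With the length trend removed as well as control replicate 4, chemokine ligands (adjusted p = 0.0743) and M1-type genes (0.120) were no longer called, while NF-kB (0.0201) and interferon-stimulated genes (0.0109) were (both 0.899 with an estimated correlation). Splitting the remaining 5 libraries into 2 and 3 in all 10 ways, only 1 split, the real one, called all 4 lists as lower, and the highest other split called 2. The split of CXCL10 replicates 3 and 4 against the other 3 libraries also called 4 lists, lower in that pair. By list score, CXCL10 replicate 1 lay nearer controls 1 and 3 than CXCL10 replicate 3 for chemokine ligands (0.17 against -0.15) and NF-kB genes (0.11 against 0.04). It lay beside CXCL10 replicate 3 for M1-type (0.03 and 0.02) and interferon-stimulated genes (0.19 and 0.18), where CXCL10 replicate 4 was lower (-0.23 and -0.35). For interferon-stimulated genes control replicate 3, at 0.04, lay below CXCL10 replicates 1 and 3, so the groups overlapped even without control replicate 4. Control replicate 1 was at 0.44. For chemokine, M1-type and NF-kB genes controls 1 and 3 lay above all CXCL10 libraries. With another library left out the median lay above 0 for interferon-stimulated (up to 0.17), NF-kB (up to 0.09) and M1-type genes (0.02), these 10 splits are too few to reach a share under 0.05, the choice of the library left out followed from the data, and an effect of CXCL10 stays open.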
